A study of Mus musculus with 4 samples.

How the data were processed

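The series holds 4 RNA-seq libraries, 2 of purified mature dermal adipocytes and 2 of purified mature inguinal adipocytes, from C57BL/6 mice at postnatal day 30. Per the labels' protocols, tissue was digested with collagenase IV and dispase II, adipocytes were collected by flotation in a centrifuge, RNA was extracted with Trizol and a column kit, and libraries were made from DNase-treated total RNA with a stranded total RNA kit. The submitters' processing notes name bcl2fastq, FastQC, TopHat2 2.0.12, Picard 1.127, featureCounts (Subread 1.4.6), edgeR and the mm10 genome, without roles or settings. The strand setting of the counting is not given in the sources used here, so reads of genes with an antisense neighbour may not be separable. Total RNA libraries also carry unspliced and noncoding RNA, and mature adipocytes that float can carry attached cells and free RNA of other cell types.

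The deposited signal values are gene-level CPM that the authors scaled by a library total and a further factor, because the columns sum to between 960745 and 1074951 and not to 1 fixed total. In each column the values were whole multiples of 1 step, the value of 1 read, for 100% of genes within 0.001 of a whole number. The recovered reads numbered 10794480 and 10127125 in the dermal and 12730013 and 10165094 in the inguinal libraries, and 1 read was worth 0.0844 to 0.0969 CPM. The factors implied by the deposited columns were 1.02, 1.04, 0.930 and 1.01, equal to the trimmed mean of M values factors recomputed from the reads to the digits given. A level of 3 reads corresponded to 0.253 to 0.291 CPM. Between 16143 and 16967 genes had at least 1 read per library, and the 50 most abundant genes took 24.5% to 27.9% of reads. Intervals on ratios of reads cover counting error only.

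Groups were taken from the sample titles. Libraries of one depot correlated at 0.987 (dermal) and 0.982 (inguinal) on the log2 scale across genes, which are not independent replicates, and their read counts differed far beyond sampling noise, so no library was counted as a duplicate. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 76.4% of the variance and separated the depots, and the second held 17.7% and separated replicate 1 from replicate 2 of both depots. The values of each gene did not overlap between depots for 61.8% of tested genes, where chance gives 33.3%.

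Genes with a CPM of at least 1 in at least 2 of the 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5) with an intensity trend, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on that scale understates the change of low genes. A count test was not the main test because the deposited values are normalized, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. They called 2056 and 1985 genes, against 2094 with limma. Counts were simulated with the real library sizes, and 12751 simulated genes passed the filter. The limma test recovered 54.5% of genes changed by 1 and 88.9% of genes changed by 2 on the log2 scale. It made 17 false calls among 168 (10.1%), more than a threshold of 0.05 is meant to allow. The calls in the real libraries may therefore also hold more false ones than that threshold implies. The list test called the planted list and 0 of 40 unchanged lists. Simulated genes varied independently, so the 0 of 40 does not cover lists of correlated genes. In the real libraries the same list test called 10 lists higher in replicate 1 and 10 in replicate 2, of 43.

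Before the data were examined, 45 gene lists with 1268 members were fixed, covering adipocyte functions and markers of other cells that the preparations could hold, together with the tests, their alternatives and the rule for named genes. Of these lists 43 were tested with camera at a preset correlation of 0.01, adjusted over the lists. The other 2 lists, of sex-linked genes, served to check labels. Camera with an estimated correlation was run as an alternative and, with 2 residual degrees of freedom, had little power. The rule named the 10 genes with the largest log2 fold change in each direction among those that passed, had a mean of at least 10 CPM in the higher depot and did not overlap between depots. It also named, for each described list that passed or had at least 3 members passing, the 2 members with the smallest adjusted p and the 2 with the highest mean. A fixed set of adipocyte, skin, immune, positional and sex-linked genes was named in any case, of which Krt18 is not analysed here, and Krt14 and Xist fell below the filter. It named 134 tested genes, of which the text prints a part. A further 29 genes were named after their values were seen, of which Cebpa, Twist1 and Meox2 appear in the plot of values by library alone. Gene positions came from GENCODE M21 on GRCm38, to which 18496 of 18781 genes (98.5%) matched by symbol, and Python was used for figures. Alternatives covered the pseudocount, the filter, the scaling, a replicate block, the variance model, the count tests, a minimum fold change, each library left out in turn, and the list test. An analysis of function lists without any member of the cell type lists, and one of lists between replicate numbers with an estimated correlation, were chosen after seeing the data.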

Results

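RNA was sequenced from mature adipocytes purified from 2 fat depots of C57BL/6 mice, a common inbred strain, at postnatal day 30. Dermal adipocytes came from the fat layer of the dorsal skin, which lies next to the hair follicles, and inguinal adipocytes from the subcutaneous fat pad of the groin. Each depot gave 2 libraries. The reads assigned to genes numbered 10794480 and 10127125 in the dermal libraries and 12730013 and 10165094 in the inguinal libraries. The table listed 18781 genes, of which 12797 passed the expression filter and were tested. Values below are normalized CPM, read counts scaled to library size, as mean ± SD with n = 2 per depot, and log2 fold changes are dermal over inguinal on the log2(CPM + 0.5) scale. Y-linked transcripts were detected in all 4 libraries, with Ddx3y at 169.8 ± 1.94 CPM in dermal and 245 ± 5.92 CPM in inguinal libraries, whereas the X-inactivation transcript Xist had at most 2 reads in any library.

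The comparison asked how the transcriptome of dermal adipocytes differs from that of inguinal adipocytes at an age when, per the labels, dermal fat is abundant. Dermal libraries carried higher levels of the Iroquois genes Irx1, Irx2 and Irx5, which encode homeodomain transcription factors, of the BMP antagonist Nog, and of macrophage-associated transcripts such as the chemokine gene Ccl4 and the complement gene C1qc. Inguinal libraries carried higher levels of Ucp1, the uncoupling protein of thermogenic fat, of Cidea, a lipid droplet protein abundant in brown fat, of immediate early genes such as Fosb, and of endothelial markers such as Kdr, the main VEGF receptor. Among transcripts of mature adipocytes, Adipoq, Pparg and Retn did not pass as different, whereas Lep, which encodes leptin, was higher in dermal libraries. In total 968 genes were higher in dermal and 1126 higher in inguinal libraries (limma, Benjamini-Hochberg adjusted p below 0.05, two-sided). Of these, 533 and 735 differed at least by 1 on the log2 scale. The remaining 10703 genes did not pass.

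The largest differences that met the selection rule for named genes were led in dermal libraries by Ccl4, at 47.6 ± 7.28 CPM against 2.34 ± 0.155 CPM (log2 fold change 4.07, SE 0.20, adjusted p = 0.000664). It was followed by the major urinary protein gene Mup20 (log2 fold change 3.96), the desmosomal gene Dsp (3.89), the predicted gene Gm20554 (3.81), Irx1 (3.58), the neuritin gene Nrn1 (3.52), Nog (3.50), Irx5 (3.49), Irx2 (3.47) and Grb14, an adaptor of the insulin receptor (3.46). In inguinal libraries Ucp1 led, at 44.0 ± 24.8 CPM, from 948 reads, against 1 read in the dermal libraries. Its ratio of normalized levels was 921 with a 95% counting interval of 165 to 36416, and its fitted log2 fold change was -6.23 (SE 0.41, adjusted p = 0.00140), or -6.83 without inguinal replicate 1 and -5.63 without inguinal replicate 2. Cidea (-4.71), the chemokine gene Cxcl9 (-4.28), the transcription factor gene Gata6 (-3.88), the interferon-inducible GTPase gene Iigp1 (-3.73), the collagen gene Col28a1 (-3.72), Gm4841 (-3.53), Vwa3a (-3.43), the matrix gene Tnc (-3.42) and Lnx1 (-3.39) followed. Col28a1 lay at -4.31 without inguinal replicate 1 and -3.13 without inguinal replicate 2, and Dsp at 3.05 without dermal replicate 1 and 4.74 without dermal replicate 2. In the GRCm38 (mm10) assembly, Ucp1 lies on chromosome 8, 83290352 to 83298452, Cidea on chromosome 18, 67343604 to 67367785, Cxcl9 on chromosome 5, 92321347 to 92328079, and Ccl4 on chromosome 11, 83662584 to 83664683. Irx1 (chromosome 13, 71957921 to 71963723) and Irx2 (chromosome 13, 72628820 to 72634198) share a gene cluster with Gm20554, and Irx5 lies on chromosome 8, 92357625 to 92376286. Gm20554 lies on the opposite strand to Irx2, and its start is less than 1 kb from the start of Irx2. Gata6, Cidea, Tnc, Lnx1 and Nrn1 have annotated antisense neighbours, and Mup20, Iigp1 and Gm4841 belong to multigene families, so reads could have been split or shared for these genes.

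Genes of mature adipocytes were abundant in both depots. Of 31 measured members of the adipocyte list, 4 were higher in dermal, 1 was higher in inguinal and 26 did not pass, with identical counts when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.345). Lep stood at 504 ± 22.5 CPM in dermal and 226 ± 23.8 CPM in inguinal libraries (log2 fold change 1.16, SE 0.14, adjusted p = 0.00437). Plin1, which encodes the lipid droplet coat protein perilipin, was also higher in dermal libraries (log2 fold change 0.96, SE 0.16, adjusted p = 0.0117), a call lost without dermal replicate 2 (0.84, adjusted p = 0.0850). Adipoq, encoding adiponectin, measured 3854 ± 155 against 3144 ± 254 CPM (adjusted p = 0.342), Pparg, the adipocyte master regulator, 507 ± 30.8 against 505 ± 113 CPM (adjusted p = 0.952), and Retn, Cfd and Fabp4 had adjusted p of 0.988, 0.957 and 0.181. Of 21 members of the fatty acid synthesis list, 17 had negative log2 fold changes. The 2 that passed, Elovl5 and Acot11, named after their values were seen, were higher in inguinal libraries over all genes and over the list alone. Whether these 2 calls reflect synthesis itself was not tested. The median of the 21 genes was -0.56, and the set did not pass (camera adjusted p = 0.0589). The Elovl5 call was lost without dermal replicate 2 (adjusted p = 0.135) and without the intensity trend (0.0576). Fasn (log2 fold change -0.02, SE 0.53) and Acly (-1.16, SE 0.87) varied between libraries of one depot, and were higher in replicate 1 of both depots. Acly was lower in dermal libraries within each replicate number (3117 against 7867 CPM in replicate 1, 797 against 1569 CPM in replicate 2). Fasn was not (17787 against 19109 CPM and 8561 against 8180 CPM). Scd1 measured 34813 and 36331 CPM in dermal and 62455 and 43326 CPM in inguinal libraries (adjusted p = 0.433). In the lipolysis list 3 genes were higher in dermal, 3 higher in inguinal and 15 did not pass (4 and 5 passed when adjusted over the list alone). G0s2, an inhibitor of the lipase ATGL chosen after its values were seen, was higher in dermal libraries (log2 fold change 1.79), and the antilipolytic receptor gene Hcar2 was higher in inguinal libraries (-1.65). The adipokine list held 8 members higher in dermal and 6 higher in inguinal libraries, with the same counts over the list alone. Grn, which encodes progranulin, was higher in dermal libraries (log2 fold change 1.24, SE 0.12, adjusted p = 0.00276), where macrophage markers had a median log2 fold change of 1.49. Macrophages also express Grn.

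Many thermogenic and fatty acid oxidation genes were higher in inguinal libraries. In the same libraries endothelial (median log2 fold change -1.92), red blood cell (-2.04) and immediate early genes (-1.42) were also higher. Of 23 measured brown and beige adipocyte genes, 12 were higher in inguinal and 1 was higher in dermal libraries (13 and 1 when adjusted over the list alone), with a median log2 fold change of -0.83. The set passed camera with its preset correlation (adjusted p = 0.000588) and not with an estimated one (adjusted p = 0.752 with an estimated correlation, unadjusted p = 0.0498). Besides Ucp1 and Cidea (1.97 ± 1.11 CPM in dermal, 60.7 ± 3.75 CPM in inguinal), the members that passed included Ebf2, a beige and brown fat transcription factor (-2.76), Cpt1b, a carnitine palmitoyltransferase (-2.59), and Ppargc1a, a coactivator of mitochondrial genes (-1.26), 3 examples chosen after their values were seen. The member higher in dermal libraries was Zic1, a developmental transcription factor gene used as a brown fat marker, with 166 reads in dermal and 1 read in inguinal libraries (ratio 171, 95% counting interval 30.2 to 6789). Zic1 overlaps Zic4 on the opposite strand. Among 24 fatty acid oxidation genes, 11 were higher in inguinal and 1 in dermal libraries (13 and 1 over the list alone), including Pdk4, a brake on glucose oxidation (-2.45), and the acyl-CoA dehydrogenase gene Acadl (-1.02). This set gave a camera adjusted p = 3.33e-05, and adjusted p = 0.752 with an estimated correlation. The 53 nuclear genes of the respiratory chain shifted slightly as a set (median -0.31, camera adjusted p = 0.000257, adjusted p = 0.819 with an estimated correlation), although 3 members passed singly and 0 did when adjusted over the list alone. That set call ended without inguinal replicate 1 (adjusted p = 0.134). Cholesterol synthesis genes showed a median of -0.44 with 2 of 25 members, Hsd17b7 and Fdft1, higher in inguinal libraries over all genes and over the list alone (camera adjusted p = 0.0315, adjusted p = 0.819 with an estimated correlation). The cholesterol call ended without a filter (adjusted p = 0.0603), without dermal replicate 2 (adjusted p = 0.110) and without inguinal replicate 1 (0.910). Both gene calls were lost without dermal replicate 2 (adjusted p = 0.0528 for Hsd17b7 and 0.0931 for Fdft1), and that of Fdft1 also without dermal replicate 1 (0.0891) and without the intensity trend (0.0617).

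**Figure D1:**
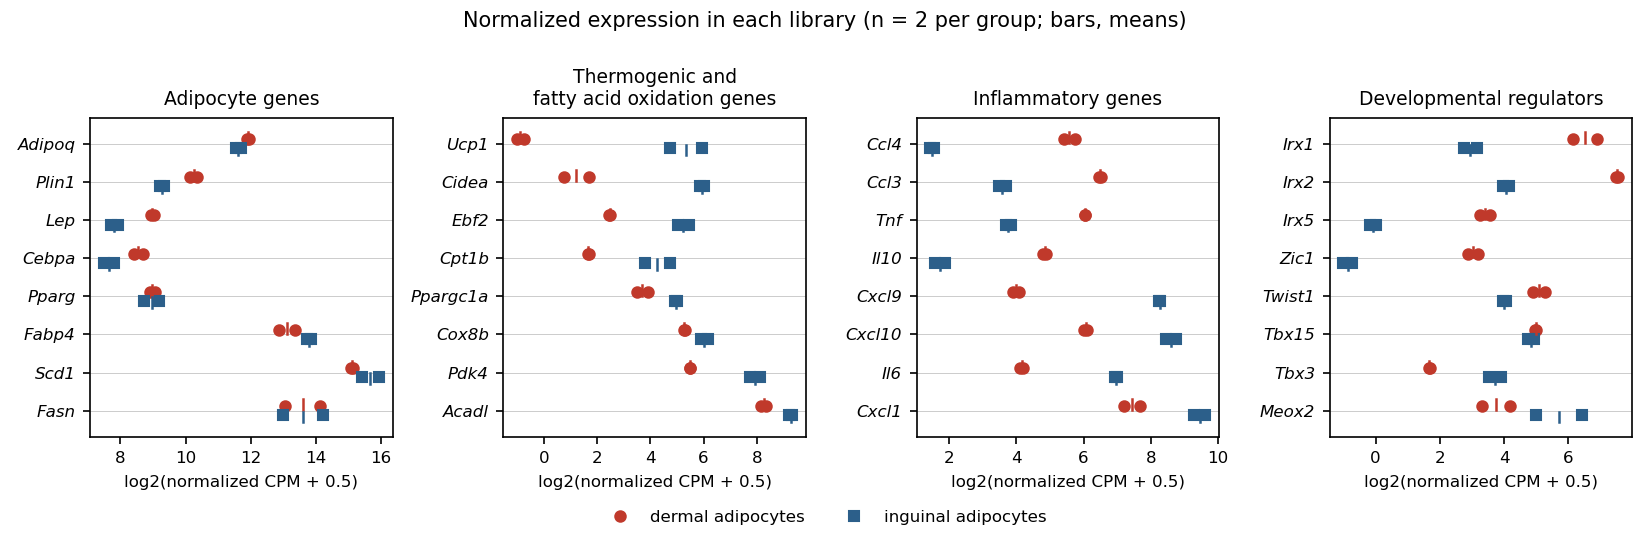
Normalized expression of 32 genes in each library on a log2(CPM + 0.5) axis, with circles for the 2 dermal libraries, squares for the 2 inguinal libraries and short bars for the group means of the log2 values. Ucp1 and Cidea separate the depots far more than Adipoq or Pparg do, while Fasn varies within each depot from 8561 to 17787 CPM in dermal and 8180.2 to 19109 CPM in inguinal libraries.

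Markers of other cell types also differed between the preparations, which were made by enzymatic digestion and flotation. All 30 measured macrophage markers had higher estimates in dermal libraries and 25 passed (26 over the list alone), with a median log2 fold change of 1.49 (camera adjusted p = 1.77e-15, adjusted p = 0.752 with an estimated correlation). Their reads made up 0.306% and 0.289% of the dermal libraries and 0.0992% and 0.101% of the inguinal libraries. Csf1r, the receptor for the macrophage growth factor CSF1, measured 174 ± 3.26 CPM in dermal and 55.6 ± 1.46 CPM in inguinal libraries, and the mannose receptor gene Mrc1 377 ± 20.6 and 127 ± 13.8 CPM. Complement genes, of which 9 of 21 were higher in dermal and 1 higher in inguinal libraries (10 and 1 over the list alone), included the macrophage transcripts C1qa (1.71) and C1qc (2.13), whereas the abundant adipocyte transcripts Cfd (-0.04) and C3 (-0.09) did not pass. The complement set gave a camera adjusted p = 0.00149 and an adjusted p = 0.752 with an estimated correlation. Of 10 measured genes of MHC class II antigen presentation, 5 were higher in dermal and 0 in inguinal libraries (6 and 1 over the list alone). Among the 5 were the cathepsin gene Ctss (1.55), the costimulatory gene Cd86 (1.62) and, with a smaller change, Cd74 (0.66). The Cd74 call was lost without a filter (limma adjusted p = 0.0576) and without the intensity trend (0.0835). With libraries left out in turn its log2 fold change ranged from 0.46 to 0.86. The set gave a camera adjusted p = 0.00337 and an adjusted p = 0.752 with an estimated correlation.

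Endothelial markers went the other way. Of 25 markers, 22 were higher in inguinal libraries (23 over the list alone) and all 25 estimates were negative, with a median of -1.92 (camera adjusted p = 9.79e-15, adjusted p = 0.752 with an estimated correlation). Kdr measured 72.8 ± 0.290 CPM in dermal and 347 ± 76.9 CPM in inguinal libraries, and the cadherin gene Cdh5 153 ± 22.3 and 655 ± 229.9 CPM. The endothelial reads made up 0.0916% and 0.101% of dermal and 0.271% and 0.395% of inguinal libraries. Of 17 pericyte and smooth muscle genes, 8 were higher in inguinal and 3 higher in dermal libraries (11 and 3 over the list alone, camera adjusted p = 0.00218, adjusted p = 0.752 with an estimated correlation). The smooth muscle myosin gene Myh11 had a log2 fold change of -2.31. Red blood cell genes were higher in inguinal libraries in 8 of 9 rows (9 over the list alone, camera adjusted p = 3.33e-05, adjusted p = 0.752 with an estimated correlation). In those rows the pairs Hba-a1 and Hba-a2, Hbb-b1 and Hbb-bs, and Hbb-b2 and Hbb-bt carried identical values, so the 9 rows hold 6 distinct measurements.

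Markers of skin and muscle were measured as well. Of 12 measured keratinocyte genes, 7 were higher in dermal and 1 higher in inguinal libraries (8 and 1 over the list alone, camera adjusted p = 0.00142, adjusted p = 0.752 with an estimated correlation). This set call ended with a filter at 5 CPM (adjusted p = 0.121). Summed reads of the keratinocyte list went the other way, at 0.0334% and 0.0341% of dermal and 0.0355% and 0.0438% of inguinal libraries. Most of this sum came from Itga6, so the sum mainly followed that gene. Itga6 gave 183 and 220 of 328 and 327 CPM in dermal libraries, and 338 and 393 of 382 and 432 CPM in inguinal libraries. Krt15, at 3.25 CPM in dermal and 0.0422 CPM in inguinal libraries, passed the filter through the dermal libraries alone. The member higher in inguinal libraries was the integrin gene Itga6, which endothelial cells also express, at 202 ± 25.9 CPM in dermal and 365 ± 38.5 CPM in inguinal libraries, a call lost without dermal replicate 1 (adjusted p = 0.102). Dsp measured 21.3 and 6.26 CPM in the dermal libraries and 0.253 and 0.388 CPM in the inguinal libraries, and the basal keratin gene Krt14 had 18 dermal reads and 1 inguinal read, below the filter. Of 10 hair follicle genes 6 were higher in dermal libraries and 0 in inguinal (7 and 1 over the list alone), including Tchh, which encodes trichohyalin, at 34.9 and 5.60 CPM in dermal libraries and 1.14 ± 0.303 CPM in inguinal libraries. This set gave a camera adjusted p = 0.0120, and adjusted p = 0.752 with an estimated correlation, and its call ended with a filter at 5 CPM (adjusted p = 0.0839). Tchh had a log2 fold change of 3.17, or 1.90 without dermal replicate 1 and 4.44 without dermal replicate 2. Its call was lost without a filter (adjusted p = 0.0611) and without the intensity trend (0.0666). Among 21 skeletal muscle genes, 2 were higher in dermal and 1 in inguinal libraries (1 and 1 over the list alone), and the set call (camera adjusted p = 0.0319, adjusted p = 0.752 with an estimated correlation) ended without dermal replicate 1 (adjusted p = 0.1001) or inguinal replicate 2 (0.113), with quantile normalization (0.109) and with a filter at 5 CPM (0.422). The muscle actin gene Acta1 measured 13.6 ± 1.45 against 13.1 ± 6.83 CPM. The mast cell genes Cma1, Cpa3 and Mcpt4 were higher in dermal libraries, 3 of 9 measured members with 1 higher in inguinal (4 and 1 over the list alone), and the set did not pass (camera adjusted p = 0.111). The calls of Cma1 (adjusted p = 0.0582) and Cpa3 (0.0578) were lost without the intensity trend. Cpa3 had a log2 fold change of 2.63, or 3.40 without dermal replicate 1, 1.86 without dermal replicate 2, 2.02 without inguinal replicate 1 and 3.24 without inguinal replicate 2.

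Cytokine and chemokine genes split between the depots. Of 34 measured inflammatory genes, 9 were higher in dermal and 15 higher in inguinal libraries (11 and 15 over the list alone), and the set did not pass (camera adjusted p = 0.834), with a median of 0.07 and a mean of -0.07 on opposite sides of 0. Genes higher in dermal libraries, alongside the macrophage markers, were Ccl4, Ccl3 (2.90), Tnf (2.27) and Il1b (1.90), the last 3 chosen after their values were seen. Il6, at 17.5 ± 0.774 CPM in dermal and 124 ± 3.40 CPM in inguinal libraries, Cxcl1 (-2.01) and Cxcl9 were higher in inguinal libraries, where endothelial reads were also higher. Type I interferon response genes numbered 12 higher in inguinal and 5 higher in dermal libraries of 35 (20 and 6 over the list alone, camera adjusted p = 0.00257, adjusted p = 0.752 with an estimated correlation). Irf1, a transcription factor gene that interferon-gamma induces, was higher in inguinal libraries (-2.42), and Oasl1, which lies antisense to Gm13822, was higher in dermal libraries (3.11). The interferon set call ended without dermal replicate 2 (adjusted p = 0.0852). Of 13 antimicrobial genes 5 were higher in dermal and 3 in inguinal libraries (7 and 5 over the list alone, camera adjusted p = 0.391). Camp, the cathelicidin gene, had 100 dermal and 2 inguinal reads (ratio 51.5, 95% counting interval 13.9 to 431), with a log2 fold change of 2.99 that was 3.72 without dermal replicate 1 and 2.26 without dermal replicate 2. Camp is also a neutrophil marker, and of 8 measured neutrophil markers 3 were higher in dermal and 0 in inguinal libraries over all genes and over the list alone (camera adjusted p = 0.0598). Csf3r, the receptor of the neutrophil growth factor G-CSF, was at 1.81, a call lost without dermal replicate 2 (adjusted p = 0.0723). Without cell type genes 3 antimicrobial genes were higher in dermal and 3 in inguinal libraries (camera adjusted p = 0.959). Lyz2 was higher in dermal (1.42) and Saa3 higher in inguinal libraries (-2.03). Ptprc, the pan-leukocyte marker CD45, was higher in dermal libraries (log2 fold change 0.89, SE 0.17, adjusted p = 0.0207), a call lost without dermal replicate 1 (0.73, adjusted p = 0.135).

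Immediate early and dissociation-stress genes were higher in inguinal libraries in 23 of 36 members, against 2 higher in dermal libraries (30 and 2 over the list alone). Their median log2 fold change was -1.42 (camera adjusted p = 1.38e-11, adjusted p = 0.752 with an estimated correlation). Fosb measured 107 ± 17.5 CPM in dermal and 563 ± 60.6 CPM in inguinal libraries, and Klf6 485 ± 67.9 and 1322 ± 102 CPM. The exceptions were the heat shock genes Hspa1a (1.34) and Hspa1b (2.04), near-identical paralogues that were higher in dermal libraries and were named after their values were seen. The inguinal libraries with these higher values also had the higher endothelial share of reads given above. Glucocorticoid-responsive genes were higher in inguinal libraries in 8 of 17 cases and higher in dermal in 1 (10 and 2 over the list alone, camera adjusted p = 0.00142, adjusted p = 0.752 with an estimated correlation), including the kinase gene Sgk1 (-1.92). Among 20 circadian clock genes, 5 were higher in inguinal and 0 in dermal libraries, over all genes and over the list alone, with Nfil3, a transcriptional repressor, at -1.86. The circadian set call (camera adjusted p = 0.0459, adjusted p = 0.752 with an estimated correlation) ended without dermal replicate 1 (adjusted p = 0.0868), without inguinal replicate 2 (0.181), with quantile normalization (0.0778), with a filter at 5 CPM (0.0819) and with camera on ranks (0.0567).

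**Figure D2:**
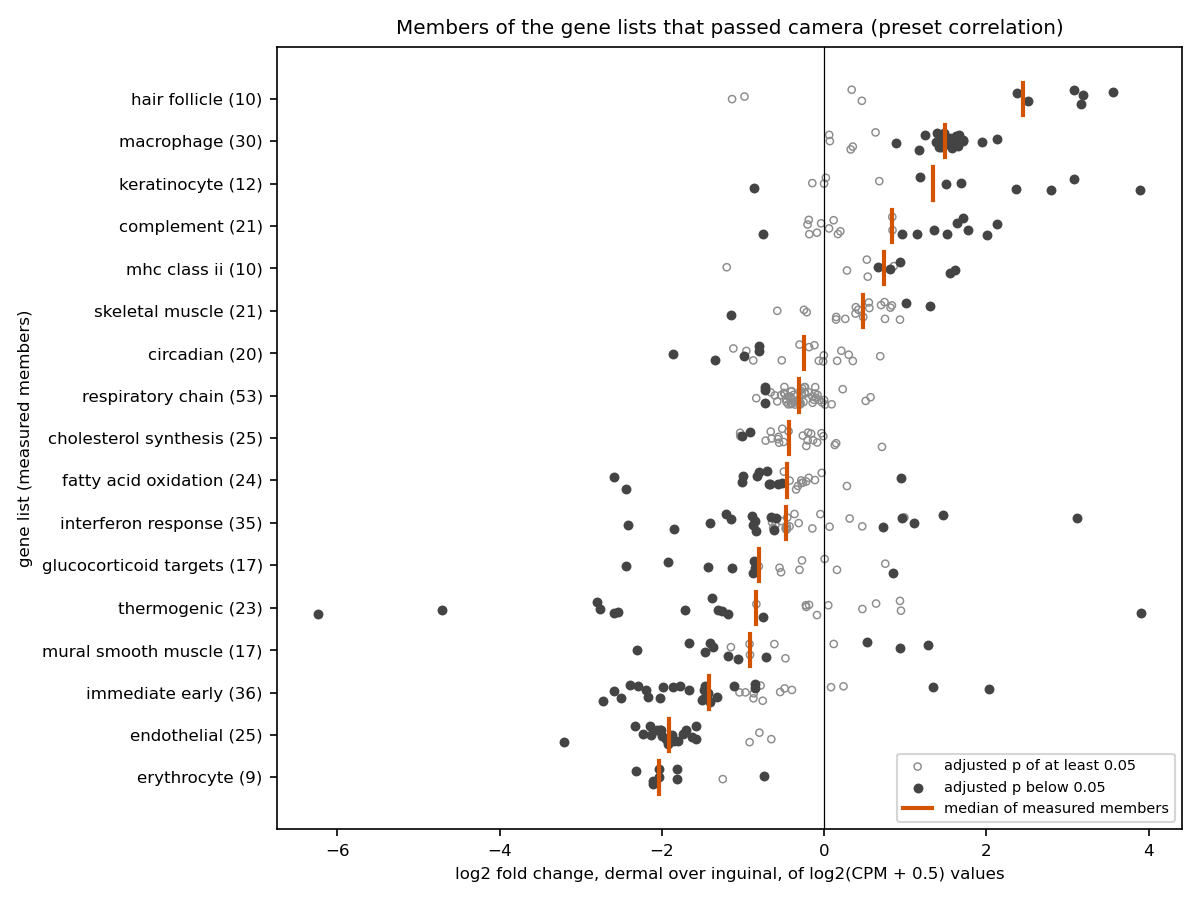
Log2 fold changes, dermal over inguinal, of the measured members of the 17 gene lists that passed camera with its preset correlation, with filled points for members with an adjusted p below 0.05, open points for the others and orange bars for list medians. All 30 macrophage members lie above 0, and all 25 endothelial members and all 9 red blood cell rows below 0. Each of the other lists shown has members on both sides.

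Developmental and matrix lists did not pass as sets but held members that differed in level between depots. Of 28 regional transcription factor genes, 8 were higher in dermal and 4 higher in inguinal libraries, with the same counts over the list alone (camera adjusted p = 0.394, median -0.06 and mean 0.33). Irx2 measured 183 ± 6.02 CPM in dermal and 16.1 ± 1.51 CPM in inguinal libraries, and Tbx3 (-2.05), named after its values were seen, was higher in inguinal libraries. Tbx15, Hoxc10 and En1, each used to mark position along the body, had log2 fold changes of 0.15, 0.02 and 0.99 and did not pass. Among 19 Hox genes of the anterior and middle paralogue groups, 4 were higher in dermal and 3 in inguinal libraries, with the same counts over the list alone (camera adjusted p = 0.292). Hoxd3 (2.51) and Hoxd4 (adjusted p = 0.00937), which overlap each other on the same strand, were higher in dermal libraries. Of 25 secreted hair cycle regulators, Nog was the single gene higher in dermal libraries and 7 were higher in inguinal libraries (2 and 7 over the list alone, camera adjusted p = 0.499, median 0.02 and mean -0.14), including Bmp6 (-2.29). Collagen and matrix genes were higher in dermal libraries for 16 of 63 members and higher in inguinal libraries for 8 (20 and 9 over the list alone, camera adjusted p = 0.0535). The basement membrane gene Nid2 (1.83) was higher in dermal libraries, and the matricellular genes Thbs1 (-2.91) and Tnc were higher in inguinal libraries. Col1a1, at 1026 ± 704 against 271 ± 158 CPM, did not pass in the main fit without a replicate block (adjusted p = 0.0733). The progenitor marker Pdgfra did not pass either (adjusted p = 0.832). Within each replicate number Col1a1 was higher in the dermal library, at 528 against 159 CPM in replicate 1 and 1524 against 382 CPM in replicate 2. The log2 fold change of Col1a1 was 1.86, and it passed without dermal replicate 1 (2.62, adjusted p = 0.00856) and without inguinal replicate 2 (2.49, adjusted p = 0.00336). The log2 fold change was 1.10 without dermal replicate 2 and 1.23 without inguinal replicate 1.

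Of the 43 lists tested, 6 passed camera as higher in dermal and 11 as higher in inguinal libraries with the preset correlation of 0.01. With an estimated correlation 0 passed, with 1 list at an unadjusted p below 0.05, and 0 passed by fry. Camera with an estimated correlation rests here on 2 residual degrees of freedom and has little power. Macrophage markers, with all 30 estimates higher in dermal libraries, had an unadjusted p = 0.0723 in it. A list that failed in that form is therefore neither supported nor excluded by it. Without dermal replicate 1 the gene counts were 455 higher in dermal and 568 higher in inguinal libraries, and without dermal replicate 2 they were 339 and 698. Another setting left the 50 most abundant genes out and rescaled to the remaining reads, without the further factor of the deposited values. It moved the share of calls higher in dermal from 46.2% to 57.5%, and the median log2 fold change of all tested genes from 0.02 to 0.11. Because the genes and the scaling factor changed together, this shift cannot be assigned to the abundant genes.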

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

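Removing cell type genes from the function lists and an estimated correlation for lists between replicate numbers were chosen after seeing the data, and all other alternatives before. Counts of genes higher in dermal and in inguinal adipocytes, 968 and 1126, became 2342 and 2384 with the replicate block, and 34 and 67 when differences were tested against a log2 fold change of 1, which asks for a larger effect. Replicate numbers are shared by titles only. Deviations of same-numbered libraries correlated at 0.464 across genes, and with 2 pairs this does not establish pairing. Leaving out 1 library gave 339 to 1212 and 568 to 1470, lowest without a dermal library (455 and 568 without dermal replicate 1, 339 and 698 without dermal replicate 2). A lone library was then assumed to vary like the other group, and replicate numbers were no longer balanced between depots. Without a filter the counts were 736 and 908, with edgeR 923 and 1133, and with DESeq2 823 and 1162. In every gene-level setting run, 0 of the calls that were shared with the main test reversed. Lists higher in dermal libraries numbered 6, and 7 to 11 with a library left out (11 without dermal replicate 1), and those higher in inguinal libraries 11, and 9 to 12. With the replicate block 20 lists passed, and each of the 17 list calls held. Of these 17, 13 held with a filter at 5 CPM, 15 with quantile normalization, 16 without a filter and 16 on ranks. With an estimated correlation both counts were 0, and by fry, which does not compare a list with other genes, also 0 and 0. Function lists without cell type genes gave 2 higher in dermal and 8 higher in inguinal libraries, against 2 and 7 with those genes. Both were adjusted over the function lists alone, by which the circadian call is lost when they are kept (adjusted p = 0.0508). Of 163 named genes, 124 passed, and 107 of these kept their call in each setting except the test against a fold change of 1 and the left-out libraries. Without dermal replicate 1, 103 kept it, without dermal replicate 2, also 103, without inguinal replicate 1, 121, and without inguinal replicate 2, 123. Signs reversed in genes that did not pass in the main test, and the cause was not tested. These were with quantile normalization Cfd (0.15), Hmgcs1 (0.081), Gsn (-0.058), Hoxc10 (-0.057), without the 50 most abundant genes Hmgcs1 (0.012), with median centring Retn (-0.0066), with edgeR Pparg (-0.0027), Retn (-0.029), with DESeq2 Fstl1 (-0.0022), Pparg (-0.0095), Retn (-0.037). With libraries left out in turn the log2 fold changes ranged over Cfd -0.36 to 0.29, Hmgcs1 -0.38 to 0.22, C3 -0.28 to 0.10, Fstl1 -0.47 to 0.51, Sncg -0.33 to 0.57, Ldb3 -0.50 to 0.0068, Myl1 -0.10 to 0.62, Acly -2.32 to 0.0061, Acta1 -0.39 to 0.68, Fasn -0.63 to 0.59, Hoxc10 -0.15 to 0.19, Pdgfra -0.64 to 0.37, Pparg -0.21 to 0.25, Retn -0.31 to 0.33.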

Other observations

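Chosen after the result was seen were the comparison of macrophage with endothelial medians, both tests of the immediate early genes and the tests of fatty acid synthesis and other lists between replicate numbers, while the tests of second marker lists, of length and GC content and of the GTPases were written before their results were seen. Interferon-gamma-inducible GTPases, which act in defence against intracellular pathogens, were lower in dermal libraries beyond Iigp1 and Gm4841. In a list of this multigene family assembled after Iigp1, Gm4841 and Tgtp2 had been noticed, all 17 measured members had negative log2 fold changes, and 15 passed (limma, adjusted p below 0.05). Without those 3 genes the other 14 had a median of -1.60, so the difference was not limited to the genes noticed first. Endothelial markers were lower in the same libraries, with a median of -1.92 beside -1.85 for all 17 GTPases. Cxcl10, another interferon-gamma target, was lower in dermal libraries (66.5 ± 3.38 against 386 ± 55.3 CPM), as was Ptx3, a secreted pattern recognition protein (42.1 ± 7.37 against 368 ± 96.1 CPM). Il10, an anti-inflammatory cytokine gene, had 28.3 ± 1.21 CPM in dermal and 2.86 ± 0.487 CPM in inguinal libraries, next to Tnf at 64.8 ± 0.0751 and 13.1 ± 1.09 CPM. Genes in this part outside the selection rule were chosen after their values were seen.

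Major urinary protein genes, which encode pheromone-binding proteins made mainly in liver, had positive log2 fold changes in 10 of 10 measured members, of which 5 passed, and 9 of 10 stayed positive with quantile normalization. Mup17 measured 29.5 ± 0.188 CPM in dermal and 5.68 ± 0.873 CPM in inguinal libraries, and Mup3 had a log2 fold change of 2.11. Many members of this family are similar in sequence, so reads of one could have been counted for another. How far this holds for each member was not tested. Fmr1, whose product is an RNA-binding protein, was among the abundant genes that differed, at 1266 ± 124 CPM in dermal and 322 ± 6.08 CPM in inguinal libraries (log2 fold change 1.97, SE 0.14, adjusted p = 0.00166). Gas6, which encodes a ligand of the TAM receptors that act in clearance of dying cells, stood at 199 ± 33.0 and 37.4 ± 7.59 CPM. Cytoplasmic ribosomal protein genes passed in 1 of 75 members (camera adjusted p = 0.391), cell cycle genes in 1 of 28 (0.6996), and hypoxia-responsive genes in 5 of 19 (0.111). Fibroblast and progenitor markers numbered 4 higher in dermal and 7 higher in inguinal libraries of 28 (camera adjusted p = 0.333), with Zfp423 at 1.00 and the tissue factor gene F3 at -1.86.

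Macrophage markers were higher and endothelial markers lower in the dermal preparations. A larger share of adipocytes that dilutes every other cell type alike would move both lists the same way, but their medians lay 3.41 apart on the log2 scale on opposite sides of 0. A second, disjoint endothelial list had a median of -1.71, with 22 of 24 members lower in dermal libraries, and a second macrophage list a median of 1.33, with 25 of 25 higher. These values are consistent with more endothelial RNA in the inguinal and more macrophage RNA in the dermal preparations, at levels of 655 ± 229.9 CPM for Cdh5 and 407 ± 16.4 CPM for F13a1, although flotation should remove most such cells. Whether this reflects the tissues themselves, cells attached to adipocytes or a different yield of the digestion was not tested, because each depot was its own preparation.

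Immediate early genes were lower in dermal libraries, with a median of -1.42. Hspa1a and Hspa1b belong both to that list and to the list of heat shock chaperones used next, so the lists were not disjoint. If a general dissociation stress in the inguinal preparations were the cause, heat shock chaperones should also be lower, but their median of -0.45 lay between the bounds set, with 14 of 19 negative, 4 passing as lower (Dnajb4, Dnaja1, Hspa8 and Bag3, -1.32 to -0.75, of which Dnajb4 alone passed with each library left out in turn) and 2 as higher (Hspa1a at 1.34 and Hspa1b at 2.04), so this cannot be told apart from no shared stress response. If endothelial RNA carried the difference, no immediate early gene should fall further than the endothelial median of -1.92 by over 0.5, yet 3 did (Fosl1, Egr2 and Maff). The bound was 3 genes, written after some of these values had been seen, but these were the most extreme genes of the pattern, 0 exceeded the bound by more than 2 SE, and the list median lay above the endothelial median, so the reading was changed, after the count was seen, from excluded to open. A difference in the tissue before digestion, such as in depot innervation or activity, remains untested.

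Libraries with the same replicate number deviated together in both depots, with a correlation of 0.467 across 12684 genes, which are not independent replicates. Transcript length and GC content do not account for it, since the correlation was 0.464 after regression on both. Of 43 lists tested with camera on the replicate term at the preset correlation of 0.01, 10 were higher in replicate 1 and 10 in replicate 2, among them collagen and matrix genes (adjusted p = 1.23e-17), cell cycle genes (1.33e-11) and immediate early genes (1.71e-06) in replicate 2, and fatty acid synthesis genes (1.98e-12), lower in replicate 2 of both depots in 18 of 21 cases, in replicate 1. The bounds written for the fatty acid synthesis test, a camera pass and most members lower in replicate 2 of both depots, were met at the preset correlation. A pass with an estimated correlation was added as a condition after the data were seen. In that form 0 lists passed and 0 had an unadjusted p below 0.05 (smallest adjusted p = 0.779). With 4 libraries that form of camera has little power, so it cannot decide. Whether a shared difference in fatty acid synthesis genes underlies the pattern therefore stays open. Acly stood at 3117 and 7867 CPM in replicate 1 and 797 and 1569 CPM in replicate 2 of the dermal and inguinal libraries. The labels do not say what same-numbered libraries share, and no biological explanation beyond these gene lists was tested.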
